A study of Mus musculus with 6 samples.

How the data were processed

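The samples were livers of 6 male C57BL/6 mice on normal chow after a 24 h fast, 3 wild type and 3 deficient in Creb3l3, described by the submitters as littermates. Each mouse gave 1 sample and 1 array, so replicates are separate animals. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column, and amplified into biotinylated cRNA, which was hybridised to Illumina WG-6 bead arrays. Groups and replicate numbers were taken from the sample titles and genotype labels. The number of arrays limits the precision.

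For each array the deposited table gives a signal per probe, the mean intensity of its beads on a linear scale, which per the file headers is an average signal and by its values is neither normalized nor background-subtracted. The same deposited tables give a detection p-value per probe, computed by the authors' software for each array, and the control bead signals behind it were not used here. Per the submitters' processing notes the software was BeadStudio 3. The authors' value table of the series also holds intensity values. Set against the array signals, its scale was linear, its columns matched quantile-normalized signals with no centring and no direction to settle, and column medians were 91.7 in the 3 wild-type columns and 91.7, 91.7 and 91.6 in the knockout columns. Its columns for wild-type replicates 2 and 3 were exchanged relative to the array tables: the column of replicate 2 matched the signals of array 3 within 0.00263 on the log2 scale, and differed from those of array 2 by up to 1.5. That table was used as an alternative only. The normalization method behind it is not given in the sources used here.

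Gene symbols came from the array tables and were updated through a gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. Of the probes, 27740 carried a current symbol, 8037 were renamed through a synonym and 9504 kept an unmatched name.

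Signals were processed with limma 3.58.1 in R 4.3.3 by neqc: normexp background correction with negative controls inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p under 0.05 on at least 3 arrays were kept, 14494 probes of 10171 genes for all 6 arrays and 14345 probes of 10055 genes for the 5 arrays without knockout replicate 3, which were normalized on their own. Genotype was the only term in lmFit and eBayes. Tests were two-sided with Benjamini-Hochberg adjustment over the kept probes and calls were made at an adjusted p under 0.05. Fits with a single knockout array assume that it varies like the wild-type arrays. Figures were drawn with matplotlib 3.10.9.

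Chosen before the data were examined were the fit of all 6 arrays, the filter, the thresholds, the gene lists, the rule for named genes and most of the other settings tried, which include leaving out each mouse. The 5 arrays without knockout replicate 3 became the basis for single genes only after the data were seen. By the rule, named genes were Creb3l3, then up to 10 rises and 10 falls with the largest log2 change among genes whose brightest probe passed and whose groups did not overlap, which gave 0 for all 6 arrays and 7 rises and 10 falls for the 5 arrays. Up to 4 members with the smallest p of each list described were added, with Apoc2, Apoa4, Apoa5, Apoc3, Fgf21 and Cidec whatever their values. A gene was represented by its probe with the highest mean signal, and other probes are given where they disagree. Some genes that the rule takes are not reported here.

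Fixed gene lists numbered 26, 17 of pathways and 9 of cell type markers. Those with at least 5 measured genes, 21 of them, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. At the preset correlation camera takes its degrees of freedom from the number of genes, and with an estimated one from the residuals, 4 for 6 arrays, 3 for 5 and 2 with a single knockout array, so that a list can lose its call there without correlated genes. Benjamini-Hochberg adjustment ran over the tested lists. The study drew genes from the lists of lipoprotein lipase modulators, apolipoproteins, lipid droplet proteins and PPARA targets, so their direction is not independent evidence.

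The steps were tested on simulated data with 14345 probes, of which 50 were set to each change. With 3 arrays a group of equal brightness, 49 of 50 probes were recovered at a log2 change of -2, 35 at -1, 35 at 1 and 50 at 2, and 6 of 14125 unchanged probes were called. When 1 knockout array was given the profile of knockout replicate 3, 0 of 50 were recovered at each of these sizes. With 3 wild-type and 2 knockout arrays, 47, 26, 26 and 44 were recovered at -2, -1, 1 and 2, and 5 unchanged probes were called. A list shifted by 0.5 was called in each case, and 0 of 20 unshifted lists were. Simulated probes varied independently of each other, so these lists do not test how camera treats correlated genes. The case with 2 knockout arrays also left out the dimness of knockout replicate 1.

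Alternatives changed the background correction, the normalization, the source of values, the filter, the variance model, array weights, the block, the threshold, the list test and the mice left out, 1 at a time. Slide as a block was not run, because the files used here name no slide.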

Results

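Liver gene expression was measured in 6 male C57BL/6 mice that were kept on normal chow and fasted for 24 h before the liver was taken. Of these, 3 were wild type and 3 were littermates deficient in Creb3l3, which encodes CREBH, a transcription factor of hepatocytes that is anchored in the endoplasmic reticulum membrane until it is cleaved. RNA of each mouse was converted to biotinylated cRNA and hybridised to 1 Illumina WG-6 bead array with 45281 probes. A single comparison follows from this design, knockout against wild type. It asks how hepatic transcripts of the fasted liver, above all those of triglyceride metabolism, differ when the factor is missing.

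The arrays differed in brightness. A detection p under 0.05 was reached by 16224, 15832 and 15504 probes on the arrays of wild-type replicates 1, 2 and 3, where 2264 would be reached by chance. On the arrays of knockout replicates 1, 2 and 3 the numbers were 11846, 15867 and 4302. Mean deposited signals were 252, 219.7 and 219 arbitrary units for the wild-type arrays and 149, 246 and 87.3 for the knockout arrays, in the same order. Across probes, which are not independent replicates, normalized log2 signals of knockout replicate 3 correlated with those of the other arrays at Pearson's r of 0.676 to 0.697, while the other 5 arrays correlated with each other at 0.973 to 0.993. No array duplicated another. The first principal component held 87.5% of the variance of the 6 arrays and set knockout replicate 3 apart, and without that array the first component, with 55.9%, set knockout replicate 1 apart.

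**Figure D1:**
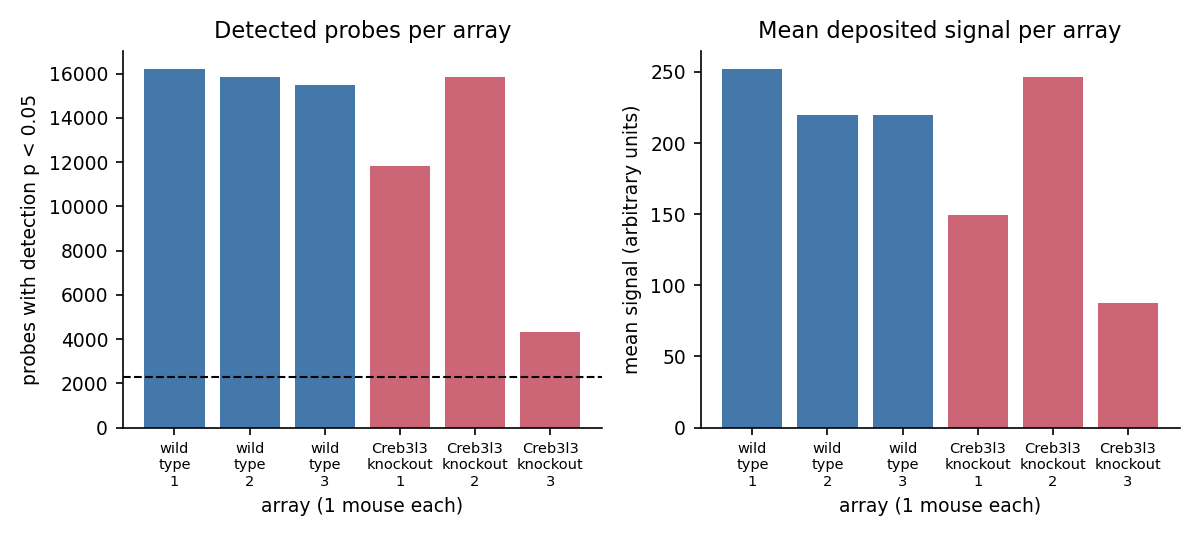
Number of probes with a detection p under 0.05 (left) and mean deposited signal in arbitrary units (right) for each array, 1 mouse each, with wild type in blue and knockout in red; the dashed line marks the 2264 probes that chance would give. Knockout replicate 3 had 4302 detected probes and knockout replicate 1 had 11846, and the other 4 arrays had 15504 to 16224.

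In the fasted knockout liver, on the arrays other than that of knockout replicate 3, transcripts of several secreted and lipid-handling proteins fell. Apoa4 fell 11.8-fold, the fasting hormone Fgf21 6.25-fold and the fatty acid desaturase Fads2 6.15-fold, and the lipid droplet protein Cidec fell below detection. Over the alternatives in those 5 arrays their log2 changes ran from -4.25 to -3.02 for Apoa4, -3.07 to -1.23 for Fgf21, -3.22 to -1.70 for Fads2 and -2.43 to -0.842 for Cidec. The desaturase Fads1, the elongase Elovl5, the gluconeogenic enzyme Pck1 and the nuclear receptor Ppara were also called lower. Over the alternatives Ppara kept its call under 4 of 16 and Fads1 under 9 of 17. Elovl5 and Pck1 each kept it under 12 of 17, and lost it without any 1 of the wild-type mice. Fewer genes rose, among them Tff3, Prepl and Esm1. In these 5 arrays 49 of 14345 tested probes passed an adjusted p of 0.05, 9 higher and 40 lower in the knockout, which stood for 9 and 32 genes. Across all 6 arrays limma called 0 of 14494 probes, with a smallest adjusted p of 0.375. In that fit 558 probes had an unadjusted p under 0.05 where chance would give 724.7. In those 6 arrays cyclic loess gave 0 higher and 3 lower, a trended and robust variance 1 and 4, and array weights 1030 and 1802. Of the weight of the knockout arrays, 87.2% fell to the dim knockout replicate 1, 11.9% to the bright knockout replicate 2 and 0.953% to knockout replicate 3. The comparison of all 6 arrays was the one fixed beforehand, as was leaving out each mouse in turn. The 5 arrays were taken as the basis for single genes and gene groups after the brightness of knockout replicate 3 had been seen.

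Creb3l3 itself had deposited signals of 1201, 949 and 929 in wild-type replicates 1, 2 and 3, and of 148, 283 and 87.9 in knockout replicates 1, 2 and 3, the last with a detection p of 0.12. Its normalized log2 signal was 9.72 ± 0.02 (SD, n = 3) in wild type and 7.40 ± 0.07 (SD, n = 2) in the knockout, so that it fell by 2.32 ± 0.15 (SE) on the log2 scale, or 4.99-fold (adjusted p = 0.00271). Across all 6 arrays the log2 change was -2.72 ± 0.39 with an adjusted p of 0.574. Median scaling in place of quantile normalization ended the call in the 5 arrays. It gave a log2 change of -2.97 and an adjusted p of 0.175, in a range of 8.02e-05 to 0.175 over all alternatives. The position of the single Creb3l3 probe relative to the deleted part of the gene is not given in the sources used here, so its signal may not check the genotype. Knockout arrays 1 and 2 kept a signal above background.

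Under the naming rule, 10 genes stood for the falls. After Creb3l3, the others were Paqr9, a membrane protein of the progestin and adipoQ receptor family, Apoa4, Fgf21, Fads2, Cidec, Them7, 1810055G02Rik, 1190007I07Rik and 2010003K11Rik. Paqr9 fell 13.8-fold, from a log2 signal of 10.96 ± 0.39 (SD, n = 3) to 7.17 ± 0.66 (SD, n = 2), with a log2 change of -3.78 ± 0.32 (SE; adjusted p = 0.00545). Of its other tested probes, those at -3.55 and -3.92, each detected on 1 of 3 knockout arrays, were called and that at -0.38 was not. Apoa4, an apolipoprotein of chylomicrons and high-density lipoprotein, fell by 3.56 ± 0.36 (SE) on the log2 scale, from 11.24 ± 0.63 to 7.68 ± 0.48 (adjusted p = 0.013), and its other probes, at -3.84 and -3.85, fell as well. The 3 genes with only clone names fell 7.04-fold (1810055G02Rik, adjusted p = 0.00273), 6.35-fold (1190007I07Rik, adjusted p = 0.00273) and 5.71-fold (2010003K11Rik, adjusted p = 0.0255). Them7 fell 6.14-fold (adjusted p = 0.0459), and its second probe stood at -0.64 and was not called. The log2 change of Them7 was -3.48 with knockout replicate 2 alone and -1.93 with knockout replicate 1 alone. Its call was lost without any 1 of the wild-type mice, with array weights, with no filter and under median scaling. Fgf21 fell by 2.64 ± 0.33 (SE; adjusted p = 0.0255) on the log2 scale, from 7.73 ± 0.40 to 5.09 ± 0.73. Fgf21, 1190007I07Rik and 2010003K11Rik were detected on 1 of 3 knockout arrays, so their fold changes rest on signals near background. Fgf21 kept its call under 12 of 16 alternatives and lost it without wild-type replicate 2 or 3, with no filter and under median scaling. The call of 2010003K11Rik was kept under 11 of 16 and was lost without any 1 of the wild-type mice. Cidec, with 6.74 ± 0.63 in wild type and 4.41 ± 0.09 in the knockout (adjusted p = 0.0377), was detected on no knockout array. Its fold is a bound, the wild-type mean over the mean, per knockout array, of the higher of the probe's own signal and the lowest signal among detected probes. That bound was 3.95-fold in the 5 arrays and 2.10-fold across all 6, and the call was lost under 6 of 13 alternatives. For the others, log2 changes over the alternatives ran from -4.35 to -3.05 (Paqr9), -3.37 to -1.96 (1810055G02Rik), -2.84 to -1.05 (1190007I07Rik), -2.94 to -1.06 (2010003K11Rik) and -3.48 to -1.27 (Them7).

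Among the rises, 7 genes met the rule. Tff3, a trefoil peptide of mucosal tissues, rose 5.87-fold, from 4.80 ± 0.11 (SD, n = 3) to 7.35 ± 0.18 (SD, n = 2), with a log2 change of 2.55 ± 0.17 (SE; adjusted p = 0.00271). Prepl, a serine hydrolase related to prolyl endopeptidase, rose by 2.41 ± 0.22 (adjusted p = 0.0077) at its brighter probe, and its second probe stood at -0.43. Esm1, a proteoglycan secreted by endothelial cells, rose 4.34-fold (adjusted p = 0.0352). Ppl, the plakin periplakin, rose 2.6-fold (adjusted p = 0.0352). Deposited wild-type signals were 103, 99.7 and 103 for Tff3 and 108, 105 and 100 for Ppl. The medians of those arrays were 94.3, 92.1 and 91.5, so the fold changes of Tff3 and Ppl rest on wild-type signals near background. Bcl2a1d, an anti-apoptotic protein with close paralogs whose transcripts its probe may not separate, rose 2.54-fold (adjusted p = 0.0255), and LOC100047628 rose 2.24-fold (adjusted p = 0.0449). With all 6 arrays the log2 change of LOC100047628 was -0.18, the opposite direction. On the dim array of knockout replicate 1 its deposited signal was 214, below 298, 217 and 259 in wild type. That of Bcl2a1d was 132, against 143, 123 and 131, and that of Esm1 was 141, against 128, 133 and 120. On that array these rises thus rest largely on the background correction and normalization. On knockout replicate 2 the signals were 540 for LOC100047628, 266 for Bcl2a1d and 464 for Esm1. Over the alternatives in the 5 arrays log2 changes ran from 1.07 to 2.83 for Tff3, 1.43 to 2.58 for Prepl, 1.10 to 2.68 for Esm1, 0.475 to 1.73 for Ppl, 0.635 to 1.52 for Bcl2a1d and 0.467 to 1.24 for LOC100047628. Tff3 kept its call under 14 of 16 alternatives. Of 17 alternatives, Prepl kept it under 14, Esm1 and Bcl2a1d under 10, and Ppl and LOC100047628 under 8. Esm1, Ppl, Bcl2a1d and LOC100047628 each lost it without any 1 of the wild-type mice.

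**Figure D2:**
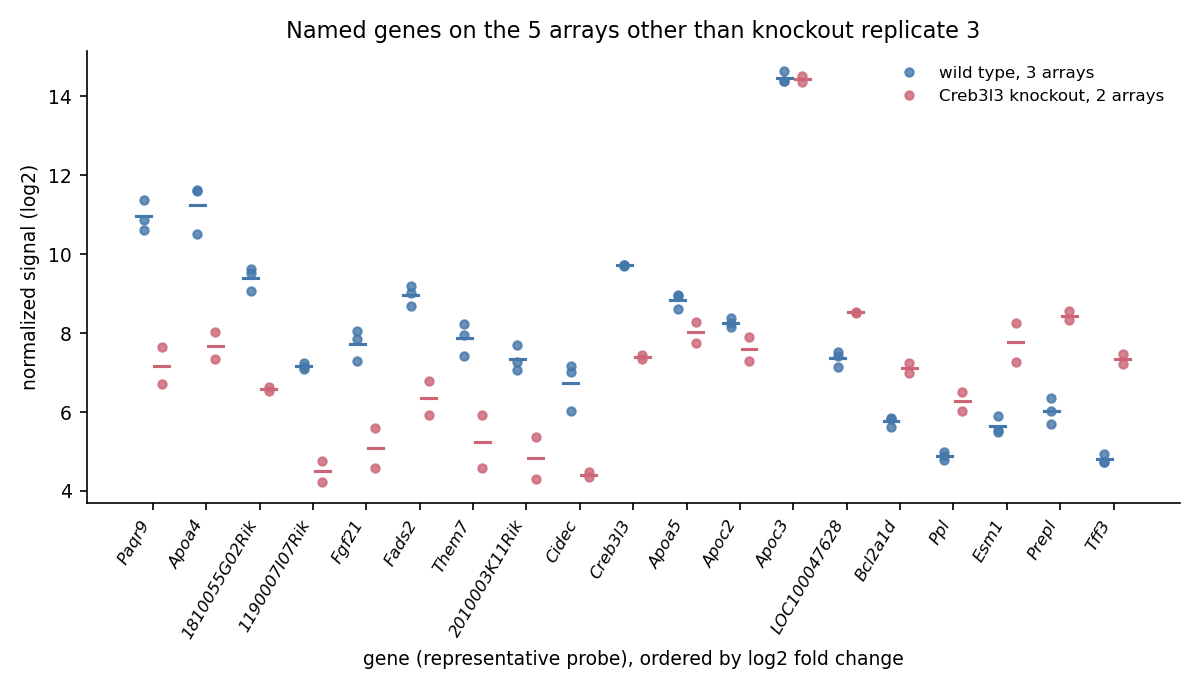
Normalized log2 signal of genes named for their rise or fall, and of Apoc2, Apoa5 and Apoc3, on the 5 arrays other than that of knockout replicate 3, with wild type in blue (3 arrays), knockout in red (2 arrays), a point for each array and a short line for each group mean. Apoa4 had means of 11.24 in wild type and 7.68 in the knockout, Tff3 had 4.80 and 7.35, and Apoc3 had 14.46 and 14.44; the direction of Apoc3 turned under cyclic loess.

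Of the 49 probes, 48 had the same direction across all 6 arrays, 41 of them with an unadjusted p under 0.05 and 0 called. With knockout replicate 2 as the lone knockout array, 48 of the 49 could be tested, all 48 had the same direction and 33 were called. With the dimmer knockout replicate 1 alone 48 were called. The 49 had been chosen as called in a fit of these same arrays, so agreement in direction was largely fixed in advance and is not independent evidence. The number of calls depended on single mice. It was 2 higher and 13 lower without wild-type replicate 1, 1 and 8 without wild-type replicate 2, and 2 and 7 without wild-type replicate 3. It was 13 and 28 without knockout replicate 1 and 787 and 1447 without knockout replicate 2. Of the 17 genes named for their rise or fall, the call was kept by 9 of 16 tested without wild-type replicate 1, 5 of 16 without wild-type replicate 2, 7 of 16 without wild-type replicate 3, 15 without knockout replicate 1 and 17 without knockout replicate 2. Creb3l3, Paqr9, 1810055G02Rik, 1190007I07Rik and Tff3 were called whichever of the 5 mice was left out. Cyclic loess in place of quantile normalization gave 25 higher and 58 lower. Median scaling, which moved the median log2 change of all tested probes to -0.42 in the 5 arrays and to -0.87 in the 6, gave 0 and 4. Testing every probe without a detection filter gave 0 and 1.

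The study's central gene group, modulators of lipoprotein lipase, had 11 measured members in the 5 arrays, of which 0 rose, 1 fell (Apoa4) and 10 did not pass. Apoa5, which stimulates the lipase, had a log2 change of -0.82 ± 0.22 (SE; adjusted p = 0.241), and Apoc2, its obligate cofactor, -0.66 ± 0.21 (adjusted p = 0.324). Apoc3, an inhibitor of the lipase, stood at -0.03 ± 0.17 (adjusted p = 0.959), with a direction that turned under cyclic loess (0.30) and without wild-type replicate 1 (0.06) or knockout replicate 1 (0.03). Its deposited signals were 26481, 22572 and 22259 in wild type and 13717 and 24566 in knockout replicates 1 and 2. At this brightness quantile normalization gave wild-type replicates 2 and 3 the same value, 14.38, so a change of Apoc3 may be understated. Adjusted over the list alone, 1 member was higher, Lpl with a log2 change of 0.61 ± 0.20, and 3 were lower, Apoa4, Apoa5 and Apoc2. Under median scaling Lpl stood at -0.12, against a median of all probes of -0.42. As a set the list did not pass, with an adjusted p of 0.26 by camera. The study drew genes from this list, so its direction is not independent evidence.

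Apolipoproteins and lipoprotein assembly factors had 18 measured members, of which 0 rose, 1 fell (Apoa4) and 17 did not pass. By sign, 13 lay below 0 and 5 above. When adjusted over the list alone, 0 were higher and 2 were lower, Apoa4 and Apoa5. Apob, the structural protein of very-low-density lipoprotein, stood at -0.42 ± 0.17 (SE; adjusted p = 0.393) and Pltp at -0.56 ± 0.22 (adjusted p = 0.393). The list was lower as a set (median log2 change -0.09, camera adjusted p = 0.0283; adjusted p = 0.463 with an estimated correlation). With the brighter knockout replicate 2 alone its adjusted p was 0.0013, and with the dim knockout replicate 1 alone 0.58. It was 0.0543 without wild-type replicate 2, 0.121 under cyclic loess, 0.0551 with a replicate block in which wild-type replicates 2 and 3 were exchanged, and 0.597 across all 6 arrays. The alternatives in the 5 arrays ranged from 2.79e-05 to 0.58. The mean log2 change of the list was -0.36, well below its median of -0.09, and Apoa4 alone stood at -3.56. The mean thus rests in large part on Apoa4. The median lay inside the central range of random lists matched on mean signal, -0.0998 to 0.137. Whether the set call holds without Apoa4 was not tested. Because the study drew genes from this list, it is not independent evidence either.

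Lipid droplet proteins had 12 measured members, of which 0 rose, 1 fell (Cidec) and 11 did not pass. G0s2, an inhibitor of adipose triglyceride lipase, stood at -1.89 ± 0.34 (SE; adjusted p = 0.0922), the monoacylglycerol lipase Mgll at -0.95 ± 0.20 (adjusted p = 0.15) and Plin3 at 0.84 ± 0.20 (adjusted p = 0.203), and adjusted over the list alone 1 was higher and 4 were lower. As a set it did not pass (adjusted p = 0.153), and it holds Cidec, a gene the study is about, so it is not independent evidence.

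Fatty acid oxidation genes and other targets of PPARA had 30 measured members. Of these 0 rose, 2 fell and 28 did not pass; 25 lay below 0. The 2 were Fgf21, a hormone rather than an oxidation enzyme, and Ppara itself, the fasting-activated nuclear receptor, which fell by 1.24 ± 0.17 (SE) on the log2 scale (adjusted p = 0.0345), was detected on 1 of 3 knockout arrays and kept its call under 4 of 16 alternatives. Acsl1, an acyl-CoA synthetase, stood at -0.73 ± 0.21 (adjusted p = 0.277). Counts adjusted over the list alone were 0 higher and 3 lower. The set was lower (median -0.19, camera adjusted p = 0.000693; adjusted p = 0.463 with an estimated correlation). Its adjusted p was 0.00194 for knockout replicate 2 alone, 0.032 for the dim knockout replicate 1 alone and 0.393 across all 6 arrays, in a range of 3.43e-08 to 0.463. Fgf21 is a gene of the study, so the list is not independent evidence.

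Ketogenesis genes had 6 measured members, of which 0 rose and 0 fell in limma, with 0 higher and 2 lower at an unadjusted p under 0.05. Adjusted over the list alone the counts were 0 higher and 1 lower, Bdh1. Bdh1, which interconverts acetoacetate and beta-hydroxybutyrate, stood at -0.91 ± 0.23 (SE; adjusted p = 0.223) at its brighter probe and was called at its dimmer one with -1.38. The set was lower (median -0.33, camera adjusted p = 0.0283; adjusted p = 0.46 with an estimated correlation). The adjusted p was 0.0284 for knockout replicate 2 alone, 0.254 for the dim knockout replicate 1 alone, 0.0545 without wild-type replicate 1, 0.0551 with the exchanged replicate block and 0.235 across all 6 arrays, in a range of 0.00134 to 0.46.

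Genes of lipogenesis and triglyceride synthesis had 19 measured members, of which 0 rose, 3 fell and 16 did not pass. The 3 that fell were not enzymes of triglyceride assembly but make long polyunsaturated fatty acids: Fads2 fell by 2.62 ± 0.27 (SE; adjusted p = 0.0143), the elongase Elovl5 by 1.92 ± 0.21 (adjusted p = 0.0189) and Fads1 by 1.31 ± 0.16 (adjusted p = 0.0243) on the log2 scale. Leaving out wild-type replicate 2 or 3 ended each of these calls, and leaving out wild-type replicate 1 ended those of Elovl5 and Fads1. Fads1 also lost its call without knockout replicate 1 (adjusted p = 0.0521) and with a replicate block in either order of the wild-type mice (0.0657 and 0.0556). Over all 17 alternatives the call was kept under 14 for Fads2, 12 for Elovl5 and 9 for Fads1. Counts adjusted over the list alone were 1 higher and 3 lower. This set was lower in the 5 arrays (median -0.34, camera adjusted p = 0.00652; adjusted p = 0.457 with an estimated correlation) and across all 6 (adjusted p = 0.0178; adjusted p = 0.929 with an estimated correlation). With knockout replicate 2 alone the adjusted p was 0.00641 and with the dim knockout replicate 1 alone 0.203, in a range of 2.79e-05 to 0.457. Across 6 arrays it was 0.378 without knockout replicate 1 and 0.504 without knockout replicate 2, in a range of 5.86e-05 to 0.929.

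Cholesterol synthesis genes and other SREBP2 targets had 20 measured members. Of these 1 rose, 0 fell and 19 did not pass, and adjusted over the list alone the count was also 1 higher and 0 lower. Msmo1 stood at 0.68 ± 0.27 (SE; adjusted p = 0.393), and Insig1, which retains the SREBP complex in the endoplasmic reticulum, at 0.68 ± 0.29 (adjusted p = 0.411), or at -0.03 under median scaling, against a median of all probes of -0.42. Tm7sf2 was lower, from -1.15 to -0.206 over the alternatives. By sign, 11 members lay above 0 and 9 below, with 3 higher and 1 lower at an unadjusted p under 0.05. As a set, with a median of 0.20, they did not pass (camera adjusted p = 0.132). With knockout replicate 2 alone they were called higher, but not with an estimated correlation or by fry there. With knockout replicate 1 alone they were not called. Genes of gluconeogenesis and the glucose response to fasting had 18 measured members, of which 0 rose, 1 fell and 17 did not pass. Pck1, which commits carbon to gluconeogenesis, fell by 1.73 ± 0.21 (SE; adjusted p = 0.0227) and by 1.12 at its second probe. Igfbp1 stood at -1.29 ± 0.32 (adjusted p = 0.224) and G6pc, the catalytic subunit of glucose-6-phosphatase, at -0.78 ± 0.23 (adjusted p = 0.29). With p adjusted over the list alone, 0 were higher and 4 were lower. As a set the list did not pass (adjusted p = 0.0665). It was called lower with knockout replicate 2 alone, but not with an estimated correlation or by fry there. It was not called with knockout replicate 1 alone.

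Bile acid synthesis and transport genes had 17 measured members, of which 0 rose and 0 fell in limma, with 0 higher and 5 lower at an unadjusted p under 0.05, and 14 lay below 0. Adjusted over the list alone, 0 were higher and 3 were lower: Cyp7b1 stood at -2.02 ± 0.38 (SE; adjusted p over all probes 0.115), Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.79 ± 0.21 (0.241) and Cyp8b1, which sets the cholic acid share, at -0.69 ± 0.19 (0.25). The set was lower (median -0.16, camera adjusted p = 0.00743; adjusted p = 0.457 with an estimated correlation). This adjusted p was 0.0013 for knockout replicate 2 alone, 0.412 for the dim knockout replicate 1 alone and 0.597 across all 6 arrays, in a range of 5.64e-06 to 0.457. Genes with higher expression in male than in female liver had 17 measured members, of which 0 rose and 0 fell in limma, with 0 higher and 6 lower at an unadjusted p under 0.05. When adjusted over the list alone, 0 were higher and 5 were lower, among them Cyp7b1, which both lists hold, Serpina12 at -1.83 ± 0.48 (SE; adjusted p = 0.241), Elovl3 at -1.67 ± 0.48 (0.278) and Mup4, whose probe may also read other major urinary proteins, at -1.45 ± 0.32 (0.167). As a set they were lower (median -0.25, camera adjusted p = 0.00652; adjusted p = 0.463 with an estimated correlation). Their adjusted p was 0.00638 for knockout replicate 2 alone, 0.254 for the dim knockout replicate 1 alone and 0.597 across all 6 arrays, in a range of 1.34e-05 to 0.463.

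Acute phase and complement genes had 25 measured members, of which 0 rose and 0 fell in limma, 6 were higher and 0 lower at an unadjusted p under 0.05, and 18 lay above 0; adjusted over the list alone, 6 were higher and 0 lower. Hamp, the iron hormone hepcidin, stood at 1.38 ± 0.22 (SE; adjusted p = 0.0609), the endotoxin co-receptor gene Cd14 at 0.82 ± 0.17 (0.139), Lcn2, a siderophore-binding protein, at 2.14 ± 0.49 (0.176) and Saa3 at 1.17 ± 0.27 (0.178). Probes of Hamp and Hamp2 may each read both paralogs. The set was higher in the 5 arrays (median 0.22, camera adjusted p = 0.000693; adjusted p = 0.46 with an estimated correlation) and across all 6 (adjusted p = 0.00163; adjusted p = 0.929 with an estimated correlation). The set pointed up with either the dim or the bright knockout array alone, and dimness and genotype cannot be told apart for it. The adjusted p was 0.000199 with knockout replicate 1 alone and 0.0613 with knockout replicate 2 alone, in a range of 1.11e-05 to 0.46. Across 6 arrays it was 0.0764 without knockout replicate 1, 0.42 under median scaling, 0.206 with no detection filter and 0.75 with detection required on all arrays, in a range of 7.34e-07 to 0.929. Iron handling genes, which share Hamp with that list, had 13 measured members, 0 of which rose or fell (4 higher and 2 lower at an unadjusted p under 0.05), with 1 higher and 0 lower adjusted over the list alone. The set of iron handling genes did not pass (adjusted p = 0.0665). It was called higher with knockout replicate 2 alone, but not with an estimated correlation or by fry there, nor with knockout replicate 1 alone. Of 26 measured genes of endoplasmic reticulum stress and the unfolded protein response, 0 rose and 0 fell, with 2 higher and 2 lower at an unadjusted p under 0.05. Adjusted over the list alone 1 was higher, the asparagine synthetase gene Asns at 2.34 ± 0.43 (SE; adjusted p = 0.0992), and the set did not pass (adjusted p = 0.347).

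Kupffer cell and macrophage markers had 14 measured members, of which 0 rose and 0 fell in limma, 3 were higher and 0 lower at an unadjusted p under 0.05, and 10 lay above 0. Adjusted over the list alone, 3 were higher and 0 lower: Adgre1, which encodes F4/80, stood at 0.69 ± 0.17 (SE; adjusted p = 0.219), Marco at 0.95 ± 0.26 (0.252) and Mpeg1 at 0.71 ± 0.20 (0.265). Under median scaling Mpeg1 stood at -0.02 and C1qb, at 0.33 otherwise, at -0.41, against a median of all probes of -0.42. The set was higher (median 0.13, camera adjusted p = 0.0357; adjusted p = 0.463 with an estimated correlation). It was not called without wild-type replicate 1 (0.0711), without wild-type replicate 2 (0.118), with the dim knockout replicate 1 alone (0.254), under cyclic loess (0.0571), under median scaling (0.44), with array weights (0.0628), with detection required on all arrays (0.207), with the exchanged replicate block (0.0777) or across all 6 arrays (0.462), in a range of 0.00455 to 0.463 in the 5 arrays. With knockout replicate 2 alone it was called (0.0284), but not with an estimated correlation (0.6) or by fry (0.358) there. Markers of other liver cells did not pass as sets: the adjusted p was 0.284 for endothelial cells (14 genes), 0.669 for stellate cells and fibroblasts (10 genes), 0.153 for cholangiocytes (5 genes) and 0.153 for erythroid cells (6 genes). Erythroid markers were called lower with the dim knockout replicate 1 alone, but not with an estimated correlation or by fry there. With knockout replicate 2 alone they pointed up and were not called. In all, 8 of 21 tested lists were called in the 5 arrays, 2 higher and 6 lower, and 2 across all 6 arrays, 1 higher and 1 lower. With an estimated correlation, which leaves camera 3 and 4 degrees of freedom, 0 of 21 were called in either, with 2 and 0 at an unadjusted p under 0.05. With knockout replicate 2 alone 10 lists were called and with knockout replicate 1 alone 3, and 0 in both with an estimated correlation or by fry. By fry 0 were called in the 5 arrays, with 4 at an unadjusted p under 0.05, and 1, bile acid genes, in the 6.

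**Figure D3:**
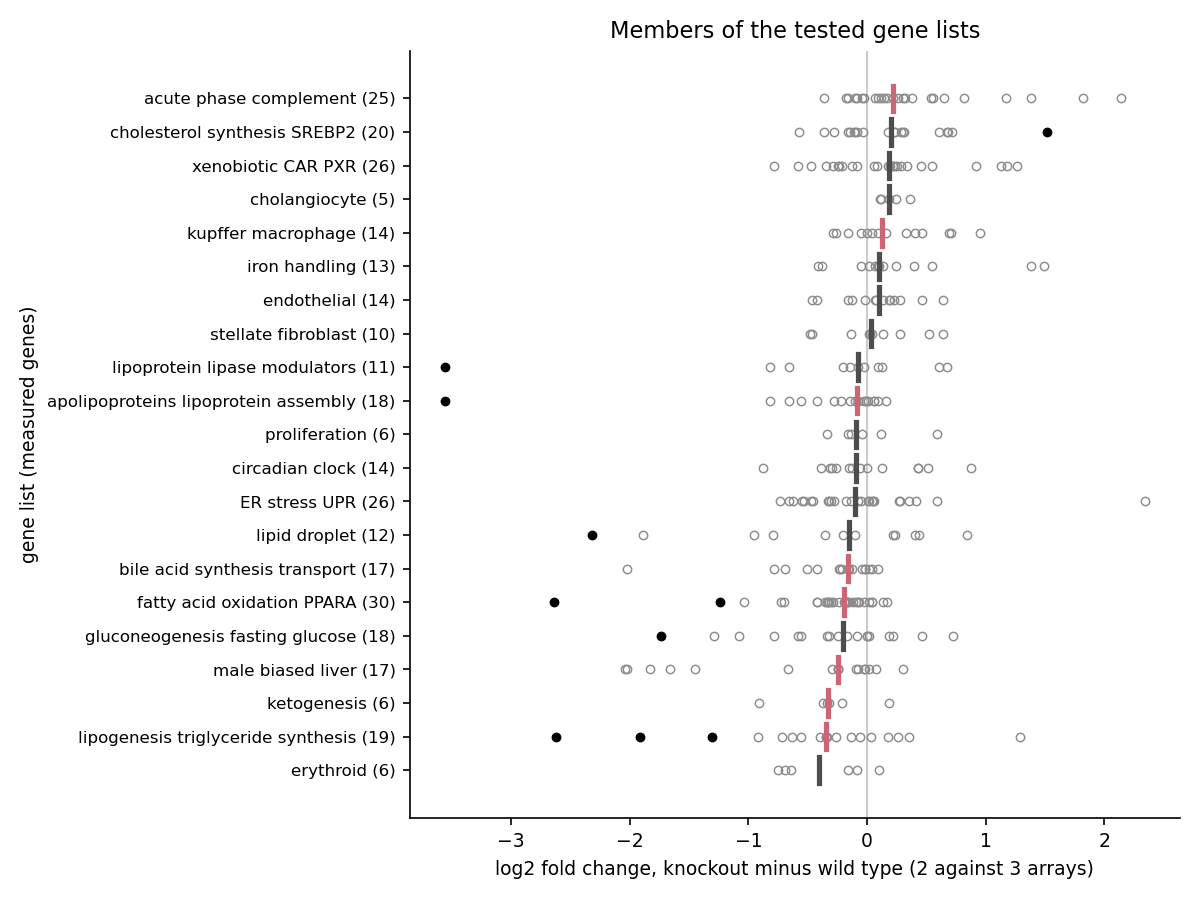
Log2 fold change, knockout minus wild type on the 5 arrays, of every measured member of the 21 tested gene lists, with filled points for members past an adjusted p of 0.05, open points for the others and a vertical bar for the list median, red where camera called the list and grey otherwise. Medians ran from -0.40 for erythroid markers to 0.22 for acute phase genes, and no list was called with an estimated correlation. Under median scaling, which moved the median of all tested probes to -0.42, Lpl, Insig1, Mpeg1 and C1qb lay below 0 but above that median.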

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

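Alternatives run on the 5 arrays without knockout replicate 3 were chosen after the data had been seen. So were the block with wild-type replicates 2 and 3 exchanged, and joint normalization of all 6 arrays before leaving out knockout replicate 3. The others were planned, among them leaving out each mouse from the 6 arrays. Knockout replicate 3, with 4302 detected probes, limited the fit of all 6 arrays. With an array of its profile 0 of 50 simulated changes of each size were recovered. The simulated array took on its whole deviation from the others, so low signal cannot be told from another distortion of that array. Across all 6 arrays, lower lists were 2 with no background correction, 2 with plain normexp and 2 with the authors' value table, and LOC100047628, at -0.18 in the reported fit, reversed to 0.11, 0.051 and 0.15. Cyclic loess gave 3 lower probes, LOC100047628 at 0.84 and Apoc3 at 1.30. Median scaling gave 0 higher and 8 lower lists, no filter 0 and 6, and detection on all arrays at p under 0.01 0 and 3. Trend and robust variance gave 1 higher and 4 lower probes and 2 lower lists. Array weights gave 1030 higher and 1802 lower probes, 3 lower lists, Creb3l3 at -2.26 and LOC100047628 at 1.08. An estimated correlation gave 0 higher and 0 lower lists and fry 0 higher. Leaving out 1 mouse gave 0 to 9 higher and 0 to 40 lower probes, 0 to 2 higher and 0 to 6 lower lists, Creb3l3 at -2.98 to -2.32, Bcl2a1d at -0.021 to 1.34 (reversed without knockout replicate 2) and LOC100047628 at -0.92 to 1.17 (reversed without knockout replicate 3), with the counts of 9 and 40 without knockout replicate 3.

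In the 5 arrays, with 9 higher and 40 lower probes reported, no background correction gave 18 and 68, plain normexp 29 and 82, the authors' values 18 and 65, and trend and robust variance 30 and 92. Cyclic loess gave 25 higher probes and Apoc3 at 0.30. Median scaling gave 0 and 4, Creb3l3 at -2.97, Lpl at -0.12, Insig1 at -0.033, Mpeg1 at -0.024 and C1qb at -0.41, with the median of all probes at -0.42. No filter gave 0 higher and 1 lower probes, with 45281 probes in the adjustment, and 5 higher lists. Detection on all arrays at p under 0.01 gave 20 higher probes and 1 higher list, array weights 26 lower probes and 1 higher list, an adjusted p under 0.1 25 higher probes and joint normalization 21. An estimated correlation gave 0 higher and 0 lower lists, as did fry. Leaving out 1 mouse gave 1 to 787 higher and 7 to 1447 lower probes, 1 to 3 higher and 2 to 7 lower lists, and Apoc3 at -0.12 to 0.065 (0.032 without knockout replicate 1), reversed without wild-type replicate 1 and without knockout replicate 1. The cause of these changes was not tested.

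Of the 17 called genes named by the rule, all kept their direction in each setting of the 5 arrays in which they were tested, and the call was kept by 13 with no background correction, 17 with plain normexp, 17 with cyclic loess, 2 with median scaling, 13 with the authors' values, 1 with no filter, 17 with trend and robust variance and 13 with array weights. Over all 64 genes followed in the 5 arrays, 907 values kept direction and side of the threshold, 107 lost a call, 52 gained one and 7 reversed. Over the 8 called lists 125 kept the call and 35 lost it.

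The labels number the mice 1 to 3 in each genotype but name no pair. Deviations of same-numbered mice from their group means correlated at -0.045, -0.048 and 0.037 in the 6 arrays. In the 5 arrays replicates 1 and 2 gave -0.132 and -0.132. These values show no pairing but cannot exclude it. Knockout replicate 3 dominated the 6 arrays, and in the 5 the deviations of knockout replicates 1 and 2 mirror each other. The exchanged order of wild-type replicates 2 and 3 was not correlated. With the replicate block 0 probes were called across 6 arrays, with 238 at an unadjusted p under 0.05. In the 5 arrays it gave 13 higher and 34 lower probes and 4 higher lists. With wild-type replicates 2 and 3 exchanged in the block, as in the authors' value table, 15 higher and 41 lower probes were called, and the lists of apolipoproteins, ketogenesis and Kupffer cell markers were not (adjusted p = 0.0551, 0.0551 and 0.0777). Which order is right was not settled. Of the 17 called genes, 15 kept the call with the block and 14 with the exchanged one.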

Other observations

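The tests of the lists with knockout replicate 1 or 2 alone were chosen only after their results had been seen. Every value from the 5 arrays rests on leaving out knockout replicate 3. Leaving out each mouse was planned, but taking these 5 arrays as the basis was a choice made after seeing the data. The genes of the next paragraph lie outside the rule for named genes and were chosen after their values were seen.

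Besides Fads1, Fads2 and Elovl5, the elongase Elovl2, which acts in the same synthesis of long polyunsaturated fatty acids, fell by 1.78 ± 0.16 (SE) on the log2 scale in the 5 arrays (limma adjusted p = 0.00749). Insig2, which like Insig1 retains the SREBP complex in the endoplasmic reticulum, fell by 1.53 at 1 probe and by 1.25 at another (adjusted p = 0.0227 and 0.0412), and its remaining probe stood at -1.05. Csrp3, a LIM protein best known from muscle, fell by 2.01 and 1.83 at separate probes (adjusted p = 0.0224 and 0.00949). Atf5, a transcription factor of stress responses, fell by 1.36 (adjusted p = 0.0446). Scp2, the sterol carrier protein, fell by 1.34 at 1 probe (adjusted p = 0.022), while its brightest probe stood at -0.50. The dimmer probe of Asns rose by 1.54 (adjusted p = 0.0236) but was detected on 1 of 3 wild-type arrays, so this change rests on signals near background. None of these was called across all 6 arrays, where 558 probes had an unadjusted p under 0.05.

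Xenobiotic metabolism genes of the CAR and PXR receptors had 26 measured members, of which 0 rose and 0 fell, also when adjusted over the list alone, and the set did not pass (camera adjusted p = 0.26). Gsta2 stood at 1.26 ± 0.33 (SE; adjusted p = 0.235) and Gsta1 at 1.13 ± 0.30 (0.245), and cross-hybridisation between these paralogs was not tested. At an unadjusted p under 0.05, 5 members were higher and 3 lower. Circadian clock genes had 14 measured members and an adjusted p of 0.964, with a median of -0.09, a mean of -0.01 and a test direction of up. Proliferation genes had 6 and an adjusted p of 0.964, with a median of -0.09, a mean of 0.00 and a test direction of up. Lists with fewer than 5 measured genes were not tested: female-biased liver genes (3 measured, 3 above 0), lymphocyte markers (4 measured, 3 above 0), neutrophil markers (2 measured, 2 above 0), pancreatic acinar markers (2 measured, 1 above 0) and adipocyte markers (2 measured, 1 above 0). Adjusted over the list alone, Ccl5 among the lymphocyte markers was higher, at 1.02 ± 0.19 (SE; adjusted p over all probes 0.116).

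The array of knockout replicate 3 was very dim. RNA of another tissue was argued against: of the 50 brightest named genes of the wild-type arrays, 50 were detected on it. Little labelled liver RNA is a candidate explanation: 99.1% of the 1235 probes with a detection p of 0 on this array lay in the top 20% of wild-type signal. Such probes are the brightest of the array by selection. The share therefore bears on whether the profile was liver-like, not on the amount of RNA. Whether less RNA, a failed labelling or a failed hybridisation lay behind it was not tested, and no biological explanation was tested.

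The second pattern is the shift of 8 gene lists in the 5 arrays, where knockout replicate 1 was dimmer than the rest. Dimness of that array as the whole cause was argued against for the lists other than acute phase. With the bright knockout replicate 2 alone 7 of these 7 kept call and direction, and with the dim knockout replicate 1 alone 1 did (adjusted p of 0.203 to 0.58 for the others). These calls are those at the preset correlation: with an estimated correlation or by fry 0 lists were called in either fit (smallest adjusted p with knockout replicate 2 alone 0.481 and 0.201). The 7 had been chosen as called in a fit that held both arrays and the same wild-type arrays, so this bears on which knockout array carried the shifts, not on whether they hold in other mice. For acute phase genes the adjusted p was 0.0613 with knockout replicate 2 alone, so dimness and genotype cannot be told apart there. A shift that depends on signal strength was tested with 10000 random lists matched on mean signal. Their medians centred on 0.00572 to 0.0229 for the 8 lists. Of the 8 list medians, 6 lay outside the central 95% of the random ones, which argues against signal strength as the whole cause for those lists. For apolipoproteins and Kupffer cell markers, whose medians lay inside, it stays open. Genotype stays open too, as a hypothesis. All 8 calls were lost with an estimated correlation and by fry. Estimated correlations were 0.124 to 0.277 for 5 of the lists, above the preset 0.01, and -0.128 to -0.00546 for ketogenesis, bile acids and lipogenesis, below it. With an estimate camera also has only 3 degrees of freedom in the 5 arrays. For ketogenesis, bile acids and lipogenesis, estimates below the preset argue against correlation as what ended the call. The fewer degrees of freedom and the adjustment over the lists remain there. For the other 5 lists which of these ended the call was not tested. Regrouped arrays also gave list calls: with 10 splits the share is never under 0.1, the real split gave 8 lists and is the 1 split with as many, and the highest of the others gave 7, with wild-type replicates 1 and 2 against the rest. That split leaves both knockout arrays on the same side, so it keeps part of the genotype contrast. Among splits that part the knockout arrays the highest gave 5 lists.

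The third pattern concerns the neighbourhood of Creb3l3. Among the 100 tested genes on each side of it, 3 of 200 were called in the 5 arrays, 1190007I07Rik (19 tested genes away), Rfx4 (31) and Fgd6 (68), against 36 of 8464 other placed genes (Fisher's exact p = 0.0604, two-sided). All 3 were lower, with log2 changes of -2.67, -1.17 and -1.83, and Rfx4, detected on no knockout array, was at least 1.84-fold lower in the 5 arrays and at least 1.01-fold lower across all 6, hardly a fall. Chromosome carried along from the strain in which the allele was made may alter such genes or the match of their probes, and with so few calls this and an effect of the factor itself cannot be told apart. The labels give only the C57BL/6 background, and the source of the allele is not given in the sources used here.

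For the other counts the 10 splits of the arrays are likewise too few for a share under 0.05. Across 6 arrays the real split called 0 probes, as did all 10 splits with a highest other of 0, and 2 lists, a number reached by 6 splits with a highest other of 6. In the 5 arrays the real split called 49 probes, reached by 1 split, and the highest of the others called 1.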
